A study of Mus musculus with 12 samples.

How the data were processed

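Mouse intestinal organoids, grown from isolated crypts in Matrigel, were profiled by CUT&RUN for acetylation of lysine 27 on histone H3 (H3K27ac), a mark of active promoters and enhancers. CUT&RUN cuts and releases the DNA beside an antibody bound to chromatin, and the released fragments are sequenced. The labels give 12 libraries in 6 groups of 2: wild type (WT) and Ptger4 knockout (KO), each with vehicle, arachidonic acid (AA, 25 µM) or prostaglandin E2 (PGE2, 50 nM). Ptger4 encodes EP4, a receptor for PGE2. The design text names a dimethyl analogue of PGE2, and the treatment length is day 3 in the sample characteristics and day 6 in the treatment protocol. Columns marked EP4KO were read as the Ptger4 KO libraries. The H3K27me3 and H3K4me3 profiles that the design text names were not analysed here.

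The deposited values are peak scores, a signal value per interval and library; per the labels, peaks came from SEACR and MACS2 on the mm10 build. The aligner, the tool settings and the normalization of the score are not given in the sources used here. The values were never negative and behaved like a mean coverage over each interval on a scale shared by the libraries. Each caller had one set of intervals scored in all 12 libraries: 166517 for SEACR (median width 1760 bp, 376 Mb in all) and 702 for MACS2 (median width 242.5 bp, 0.214 Mb in all). The SEACR intervals were the main set because they covered the genome more fully, and 701 of the 702 MACS2 intervals (99.9%) overlapped one of them. The sequencing depth is unknown, so no counting intervals were given.

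Before the data were examined, the groups, the comparisons, the tests, the rule for naming genes, the 20 gene lists and the alternatives were set, except those given here as chosen after seeing the data. Scores were analysed as log2(score + pseudocount), with the 10th percentile of the non-zero values as pseudocount (0.0579 for SEACR, 0.182 for MACS2). Intervals were kept when above it in at least 2 of the 12 libraries, which left 166471 SEACR and 701 MACS2 intervals. limma 3.58.1 in R 4.3.3 was fitted to all 12 libraries in one model of 6 groups (lmFit, then eBayes with a trend), with 6 residual and 20.1 prior degrees of freedom. Each of 9 comparisons was adjusted by the Benjamini-Hochberg method over all intervals tested, with a threshold of 0.05. All limma tests were two-sided. Errors of log2 changes are standard errors (SE), and those of scores are standard deviations (SD) between libraries.

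An interval was assigned to the nearest protein-coding gene span of GRCm38.p6 (21900 genes) within 50 kb, and 78.4% of the SEACR intervals had such a gene. The reference gives the start and end of a gene but no strand or exons. Distance to the gene span therefore replaced the planned distance to the transcription start, and a window of 2 kb around either end of the span replaced the planned promoter window. Whether an interval lies in an exon or an intron is not known here.

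The gene lists were intestinal stem cell, Wnt target, fetal-like and regenerative, YAP target, cAMP and CREB target, AP-1 subunit, eicosanoid metabolism and receptor, PPAR and fatty acid oxidation, enterocyte, goblet cell, Paneth cell, enteroendocrine, tuft cell, proliferation, interferon and antigen presentation, secretory cytokine and NF-kB, fibroblast, immune, endothelial, and housekeeping. Of 399 symbols, 396 matched the reference. Each gene was represented by its interval with the highest mean over the 12 libraries, which gave 17509 genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 20 lists within a comparison. Camera asks whether a list moved relative to all other genes, so its direction can differ from the sign of the list's own median. List levels were ranked against 10000 random gene sets of the same size and with the same spread over 10 classes of the number of intervals per gene.

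Ptger4 was named first. In each comparison and direction, the named intervals were up to 10 with the smallest p among those that passed, did not overlap between the groups and had a gene; where none passed, the 3 with the smallest p were named as not passing. Up to 4 members per list were taken by p, and of these the text gives the ones that passed within their list or led it. Some intervals and list members that these rules select are not reported here. Runs of passing intervals were first joined over gaps of up to 500 kb, a rule chosen after seeing the data; a second rule of up to 100 kb was chosen after the outcome of the first was seen. Chromosome levels were compared between genotypes by exact permutation tests over the 924 splits of 12 libraries into 6 and 6.

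The alternatives were quantile normalization, centring on each library's median, no filter, only the intervals above the median mean score, pseudocounts 4 times smaller and 4 times larger (the larger left 11024 intervals above the filter), no trend in eBayes, only the compared libraries, a block for replicate number, and leaving out each library in turn. For the lists they were all intervals per gene and only intervals within 2 kb of an end of the gene span. Cyclic loess scaling, the MACS2 intervals, quantile normalization for the gene lists, the intervals above the median mean score for the similarity of libraries, and leaving out KO PGE2 replicate 2 in comparisons that do not contain it were chosen after seeing the data. Agreement between AA and PGE2 in WT organoids was set beside 20 simulations of unchanged groups that share the same 2 vehicle libraries.

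The pipeline was tested on simulated data with 200 intervals changed by a known factor. In WT AA against vehicle, 0% were recovered at a 1.5-fold change, 1% at 2-fold and 37.5% at 4-fold. In KO against WT averaged over treatments, 1.5%, 28% and 68.5% were recovered. At 4-fold, 7 of 82 calls in the first and 11 of 148 in the second were intervals left unchanged. A planted 1.5-fold change of the fetal-like list was found in both comparisons, and none of the 19 other lists was called. The simulated noise was independent between intervals. The list tests were therefore not tried under correlation between genes. Computations also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.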

Results

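H3K27ac, a histone mark of active promoters and enhancers, was scored in 12 CUT&RUN libraries of mouse intestinal organoids. WT and Ptger4 KO organoids each received vehicle, AA at 25 µM or PGE2 at 50 nM, with 2 libraries per group. AA is the fatty acid from which cells make PGE2, and Ptger4 encodes EP4, a receptor through which PGE2 raises cAMP. The series title sets these profiles in a study of dietary AA and intestinal stemness. The labels do not say whether the libraries of a group came from separate cultures or animals, so every p-value measures only the spread between these libraries. The sequencing depth behind the scores is unknown.

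Among the 20 gene lists, over the 12 libraries together, enterocyte genes had the highest H3K27ac score and enteroendocrine genes the lowest. The order varied between groups (means of library medians). In WT vehicle the stem cell list (0.226) stood above the enterocyte list (0.214). In KO AA the immune list (0.112) stood below the enteroendocrine list (0.130). The median score of the enterocyte list (29 genes with an interval, such as Fabp2 and Apoa4) was 0.196, that of the PPAR and fatty acid oxidation list 0.194, of the stem cell list 0.184, of the fetal-like and regenerative list 0.182 and of the proliferation list 0.168, against 0.156 over all 17509 genes. The enteroendocrine list (0.116) was followed from below by the immune list and the fibroblast list (0.125), whereas the endothelial list had 0.166. Each gene was represented by its strongest interval, so the lists were also ranked among random gene sets matched in size and in the number of intervals per gene. In that ranking the enterocyte (percentile 99.9), PPAR (99.6), proliferation (98.8) and fetal-like (97.9) lists were high for their number of intervals, and the fibroblast (1.98), immune (1.84) and enteroendocrine (0.04) lists were low. The stem cell list (percentile 46.9) scored above all genes together but not above its matched sets, and the endothelial list was at percentile 32.6.

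The score varied little between intervals: the 1st, 50th and 99th percentiles of the interval means were 0.0602, 0.118 and 0.227. Library medians lay between 0.0941 and 0.122. Spearman correlations across intervals averaged 0.356 ± 0.116 (SD) between libraries of the same group, 0.338 between other groups of the same genotype and 0.322 between genotypes, so over all intervals these averages differed by less than the SD. In the 1666 strongest intervals they were 0.367 ± 0.0417 (SD), 0.318 and 0.202, and in the MACS2 intervals 0.601 ± 0.0252 (SD), 0.585 and 0.560, and in both sets the average between genotypes lay below that within groups by more than the SD. In the SEACR intervals KO PGE2 replicate 2 correlated least with the other libraries (mean 0.157), next KO PGE2 replicate 1 (0.293), and the other libraries lay between 0.322 and 0.393. In the MACS2 intervals replicate 2 correlated most (0.599), replicate 1 had 0.567, and the other libraries lay between 0.534 and 0.598.

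**Figure D1:**
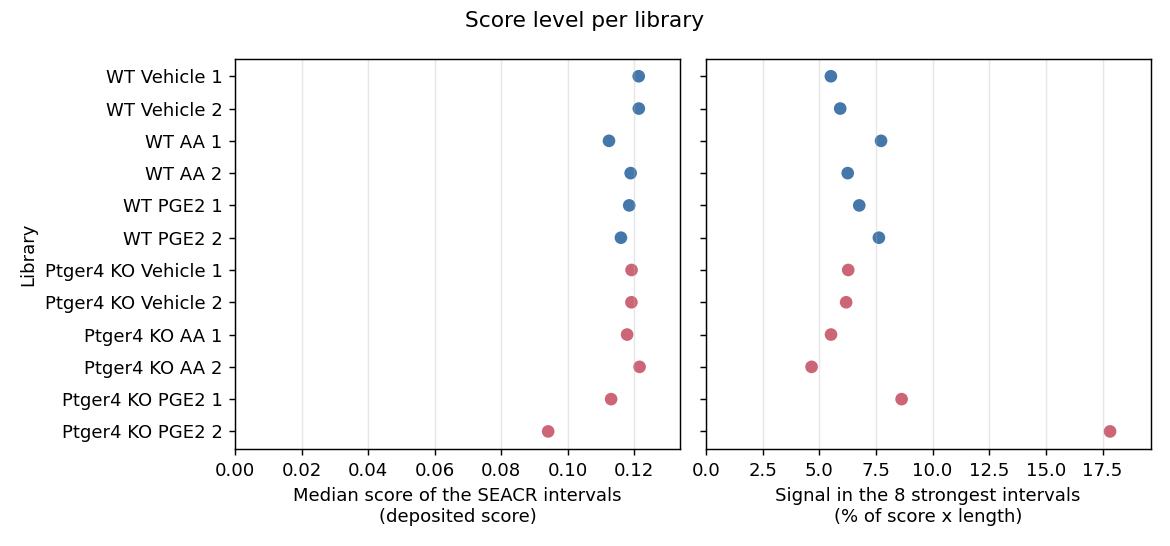
Each point is 1 of the 12 libraries; the left axis gives the median deposited score of the SEACR intervals and the right axis the percent of all signal (score times length) in the 8 strongest intervals. KO PGE2 replicate 2 has the lowest median (0.0941) and the highest share (17.8%).

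Ptger4, the gene named as knocked out, kept H3K27ac signal in the KO libraries. Within its span on chromosome 15, the interval from 5239734 to 5241902 scored 0.137 ± 0.0319 (SD, n = 6) in KO and 0.181 ± 0.0368 in WT, a log2 difference of -0.29 ± 0.14 (SE). The intervals from 5237276 to 5239274 and from 5243427 to 5245375 differed by -0.15 ± 0.17 and -0.26 ± 0.15. In limma, with Benjamini-Hochberg adjustment, none of the 9 intervals assigned to Ptger4 passed, and these had adjusted p = 0.545, 0.839 and 0.618. H3K27ac scores do not test whether the gene was deleted. Among 401 intervals within 2 Mb, 1 passed, the interval at Card6 described with the genotype comparison.

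The first question was whether AA alters H3K27ac in WT organoids. No interval passed. Among the intervals of smallest p, the score was higher with AA at Rasal2, a RAS regulator (chromosome 1, 157344904 to 157345880; log2 change 1.82 ± 0.37), and at Ncoa1, a nuclear receptor coactivator (1.33 ± 0.28). It was lower at Stat5a, a transcription factor of cytokine signalling (chromosome 11, 100859954 to 100861400; -1.41 ± 0.28), at Syne3 (-1.13 ± 0.24) and at Nckap5 (-1.54 ± 0.32). Rasal2 scored 0.287 ± 0.0469 (SD, n = 2) with AA and 0.0396 ± 0.0119 with vehicle, and Stat5a 0.0333 ± 0.0334 and 0.176 ± 0.000717. All 5 had adjusted p = 1.00 in limma. In limma 0 of 166471 intervals passed, 7590 had an unadjusted p under 0.05 (4.56%), and 0 of the 701 MACS2 intervals passed, with 38 under 0.05.

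No gene list moved past the threshold with AA in WT organoids. Among 18 stem cell genes, 13 were lower with AA and 5 higher (median log2 change -0.090), and the urea transporter gene Slc14a1 was lower by limma when adjusted over the list alone (-0.98 ± 0.25, adjusted p = 0.0128). Fosl1, an AP-1 subunit, was higher when adjusted over the list alone (1.01 ± 0.24, adjusted p = 0.00317), with 7 of 11 AP-1 genes higher. Over all intervals tested, 0 list genes passed. Of the fetal-like genes, 17 of 24 were higher (median 0.093) and of the Paneth genes 10 of 12 lower (median -0.19). The smallest adjusted camera p over the 20 lists was 0.321, shared by the stem cell, fetal-like, Paneth, tuft and interferon lists. Median and mean differed in sign for the Wnt list (0.042 and -0.034), the enterocyte list (0.038 and -0.0026) and the proliferation list (0.0057 and -0.021), and for the NF-kB list the test pointed down with a median of 0.027.

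The next question was whether PGE2 itself alters H3K27ac in WT organoids. Stem cell genes leaned down: 14 of 18 were lower with PGE2 (median log2 change -0.21), led by Smoc2 (-0.53 ± 0.20), Slc14a1 (-0.61 ± 0.25) and Lgr5 (-0.54 ± 0.24), and the list missed the threshold (adjusted camera p = 0.0818; adjusted p = 0.882 with an estimated correlation). Myc, a growth regulator and Wnt target, was lower when adjusted over the list alone (-0.72 ± 0.18, adjusted p = 0.00589), and Msln, which encodes mesothelin, was higher when adjusted over the fetal-like list alone (1.04 ± 0.28, adjusted p = 0.0226). The intervals of Smoc2 and Myc lay 22347 and 44414 bp from their gene spans. Over all intervals tested, 0 list genes passed. Of the cAMP and CREB targets, 18 of 22 were lower (median -0.16, camera adjusted p = 0.260). Of the enterocyte genes 21 of 29 were lower, and of the housekeeping genes 10 of 16 were higher (camera adjusted p = 0.249 for each).

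The stem cell result in WT PGE2 depended on how intervals were chosen and scaled. Its adjusted camera p ranged from 0.00305 to 0.882 over the alternatives. It was 0.00305 with all intervals of each gene, 0.0211 after quantile normalization and 0.0329 after cyclic loess (both scalings of the lists were chosen after seeing the data), against 0.256 with only intervals near the gene ends, 0.0783 to 0.266 when 1 compared library was left out and 0.882 with an estimated correlation. Median and mean differed in sign for the YAP (-0.034 and 0.028), enteroendocrine (-0.0048 and 0.11), tuft (0.034 and -0.051) and interferon lists (0.013 and -0.065).

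At single intervals, the score with PGE2 in WT organoids was higher at Klhdc1 (1.38 ± 0.28, adjusted p = 0.603) and at Osbpl5, a lipid transfer protein gene (1.68 ± 0.35, adjusted p = 0.603). It was lower at 3110009E18Rik (-1.51 ± 0.28, adjusted p = 0.494), at Ambn (-1.24 ± 0.23, adjusted p = 0.494) and at Gstm1, a glutathione transferase gene (-1.62 ± 0.31, adjusted p = 0.558). In limma 0 of 166471 intervals passed, with 9648 at an unadjusted p under 0.05 (5.80%), and 0 of 701 MACS2 intervals passed, with 34 under 0.05.

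Whether AA and PGE2 act alike was asked by comparing them directly, at doses that differ. AP-1 genes were higher with AA than with PGE2 (8 of 11, median log2 difference 0.26), as were enterocyte genes (22 of 29, median 0.14), and enteroendocrine genes were lower (10 of 15, median -0.21). None of these lists passed (adjusted camera p = 0.182 for each; over the alternatives the AP-1 list ranged from 0.00252, with only intervals near gene ends, to adjusted p = 0.952 with an estimated correlation). The score was higher with AA at Ncf1 (1.65 ± 0.34, adjusted p = 0.735) and at Trmt1 (1.52 ± 0.32, adjusted p = 0.735). It was lower at Atp2b1, a calcium pump gene (-1.67 ± 0.29, adjusted p = 0.676), at Ptpro (-1.68 ± 0.31, adjusted p = 0.735) and at Smo, the Hedgehog signal transducer (-0.59 ± 0.12, adjusted p = 0.735). In limma 0 intervals passed, with 8777 at an unadjusted p under 0.05, and 0 MACS2 intervals passed, with 39 under 0.05.

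The AA and PGE2 changes in WT organoids correlated across intervals at r = 0.488, and intervals are not independent replicates. Both changes are measured against the same vehicle libraries, and simulations of unchanged groups sharing them gave a mean r of 0.501 (0.497 to 0.506 in 20 simulations). The covariance was 0.0600 against 0.0577 (0.0569 to 0.0584), and 67.1% of intervals had the same sign against 66.7%. The observed r lay below every simulation and the covariance above every one.

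In KO organoids the question was whether AA acts without EP4. The score with AA was higher at 1810013L24Rik (chromosome 16, 8823147 to 8824141; log2 change 1.30 ± 0.26), at Unc5b, a netrin receptor gene (1.22 ± 0.27), and at Rec114 (1.31 ± 0.30). It was lower at Tnrc6a, which acts in microRNA silencing (chromosome 7, 123123127 to 123124521; -1.22 ± 0.23), at Ppp1r12a (-1.45 ± 0.29) and at the ubiquitin ligase gene Nedd4 (-1.79 ± 0.39). All 6 had adjusted p = 1.00. Of the proliferation genes 18 of 20 were lower (median -0.10), of the cAMP targets 18 of 22 (median -0.14), and 9 of 15 enteroendocrine genes were higher (median 0.20). The smallest adjusted camera p was 0.632, for these 3 lists, and 0 list genes passed over all intervals or adjusted over the list alone. Fabp2, a fatty acid binding protein gene of enterocytes, led its list (-0.57 ± 0.19, adjusted p = 0.193). In limma 0 intervals passed, with 6232 at an unadjusted p under 0.05 (3.74%), and 0 MACS2 intervals passed, with 26 under 0.05. The fibroblast list had a median of 0.069 and a mean of -0.023, the endothelial list -0.050 and 0.051, the Paneth list -0.0059 and 0.0083, and the eicosanoid and tuft lists had negative medians with a test that pointed up.

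PGE2 in KO organoids tested the treatment without EP4, and this group had the lowest median score over genes (0.135 ± 0.0302, SD, n = 2; the other groups had 0.153 to 0.165), a rank that replicate 2 alone (0.114) carried. Areg, which encodes the growth factor amphiregulin, was lower when adjusted over the fetal-like list alone (-0.88 ± 0.21, adjusted p = 0.00862) and over the cAMP list alone (adjusted p = 0.00790). The same held for Atf3 in the AP-1 and cAMP lists (-0.71 ± 0.22, adjusted p = 0.0184 and 0.0369), Batf in the AP-1 list (-0.95 ± 0.24, adjusted p = 0.00499), Wwc1, a Hippo regulator, in the YAP list (-0.76 ± 0.20, adjusted p = 0.0165), Bcas1 in the goblet list (-0.63 ± 0.19, adjusted p = 0.0477) and Tek in the endothelial list (-0.87 ± 0.20, adjusted p = 0.00230). The intervals of Areg and Bcas1 lay 7452 and 34179 bp from their gene spans. Over all intervals tested, 0 list genes passed. All 18 stem cell genes, 22 of 24 fetal-like genes and 20 of 21 YAP targets were lower, but so was the median of all intervals (-0.15), and that shift went to -0.013 after median centring, -0.028 after quantile normalization and 0.0087 after cyclic loess, and to -0.060 without KO PGE2 replicate 2 and -0.26 without replicate 1, so it rested largely on replicate 2. Relative to the median of all genes, the stem cell list was at -0.047 and the fetal-like list at -0.092, and the smallest adjusted camera p was 0.512. The goblet, Paneth, fibroblast and immune lists had negative medians with a test that pointed up.

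At single intervals in KO PGE2, the score was higher at Smo (chromosome 6, 29747487 to 29749343; 0.80 ± 0.12), at 9230019H11Rik (1.14 ± 0.18) and at 2210408I21Rik (1.25 ± 0.20), and lower within the span of the collagen gene Col19a1 (chromosome 1, 24299289 to 24299965; -2.34 ± 0.37), each with adjusted p = 0.0561. It was also lower at Sync (-1.46 ± 0.26, adjusted p = 0.203). Smo scored 1.18 ± 0.0342 (SD, n = 2) with PGE2 and 0.653 ± 0.0308 with vehicle. Both scores were far above the 99th percentile of interval means (0.227). The 8 strongest intervals held more of the signal in KO PGE2 replicates 1 and 2 (8.64% and 17.8%) than in any other library. In limma 0 of 166471 intervals passed, with 14445 at an unadjusted p under 0.05 (8.68%). Of the MACS2 intervals 19 passed, all higher; 15 of these lay at the start of chromosome 9, with log2 changes from 0.70 to 1.02. The SEACR interval that spans these 15 scored 72.1 in KO PGE2 replicate 2, 38.9 in replicate 1, and 29.4 and 28.7 with vehicle, so replicate 2 carried most of that gain. Without KO PGE2 replicate 1, 175 intervals passed (28 higher and 147 lower), so the lone replicate 2 carried those calls.

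Whether the treatments acted differently in the absence of EP4 was tested as an interaction. For AA, the KO change exceeded the WT change at 1810013L24Rik (1.80 ± 0.37), Smo (0.79 ± 0.17) and Mgst1 (1.59 ± 0.35), and fell short of it at Arhgap5 (-2.21 ± 0.47), Gm826 (-1.70 ± 0.36) and Wwp1 (-2.11 ± 0.45), each with adjusted p = 1.00. Slc14a1 in the stem cell list differed when adjusted over the list alone (1.56 ± 0.36, adjusted p = 0.00349). For PGE2, the KO change was below the WT change at Klhdc1 (-2.56 ± 0.39, adjusted p = 0.113) and Vxn (-2.82 ± 0.50, adjusted p = 0.245), and above it at Lhfpl2 (2.52 ± 0.50, adjusted p = 0.534), Lpar1, a lysophosphatidic acid receptor gene (2.52 ± 0.53, adjusted p = 0.563), and Sulf2 (2.35 ± 0.50, adjusted p = 0.563). Tek differed when adjusted over the endothelial list alone (-1.08 ± 0.28, adjusted p = 0.00922).

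In limma 0 intervals passed either interaction, with 6885 (AA) and 10691 (PGE2) at an unadjusted p under 0.05, and 0 of the 701 MACS2 intervals passed, with 37 and 32 under 0.05. Fetal-like genes leaned down in both interactions, 19 of 24 for AA (median -0.21, adjusted camera p = 0.232) and 21 of 24 for PGE2 (median -0.46, adjusted camera p = 0.135; over the alternatives 0.0105, with only intervals near gene ends, to 1.00 with all intervals per gene, and adjusted p = 0.982 with an estimated correlation). The median of all intervals was -0.11 in the PGE2 interaction, -0.010 after median centring, 0.0072 after cyclic loess, -0.025 without KO PGE2 replicate 2 and -0.21 without replicate 1. The stem cell list in the AA interaction had a median of -0.055 and a mean of 0.054. Without KO PGE2 replicate 2, 2 intervals passed the AA interaction and 7 the PGE2 interaction, and without KO PGE2 replicate 1, 30 passed the PGE2 interaction.

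No WT treatment call existed to follow in KO organoids. The 500 intervals of smallest p in each direction were used in its place, with 1 camera test each. Those higher with AA in WT had a median change in KO of 0.020 relative to all intervals, with 52.8% of the same sign, and those lower had 0.0074, with 48.8%. For PGE2 the values were 0.0081 with 50.8% and -0.018 with 52.6%. Camera gave unadjusted p-values of 0.749, 0.820, 0.868 and 0.387 in that order.

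Without treatment, the genotypes differed past the threshold at 1 interval. It lay 23480 bp from the span of Col19a1, on chromosome 1 from 24611402 to 24616604, and fell in KO organoids by 1.52 ± 0.19 on the log2 scale (adjusted p = 0.00247; 0.873 ± 0.0272 in KO and 2.65 ± 0.618 in WT, SD, n = 2). Its score was far above the 99th percentile of intervals (0.227). The call was lost without WT vehicle replicate 2 (adjusted p = 0.725), without either KO vehicle replicate and after median centring (adjusted p = 0.0556). The score was higher in KO, without passing, at Btaf1 (chromosome 19, 36922185 to 36929514; 1.17 ± 0.22, adjusted p = 0.406), Ncoa1 (1.45 ± 0.28) and Vxn (1.81 ± 0.35, adjusted p = 0.460). Slc14a1 was lower when adjusted over the stem cell list alone (-1.16 ± 0.25, adjusted p = 0.00188), with 13 of 18 stem cell genes lower and 0 passing over all intervals. The same 2 WT vehicle libraries enter the Slc14a1 values of WT AA, WT PGE2 and the AA interaction, so these are not independent results. The smallest adjusted camera p was 0.777. In limma 7569 intervals had an unadjusted p under 0.05 (4.55%), and 3 MACS2 intervals passed, all lower, 2 of them near Col19a1. Without KO PGE2 replicate 2 in the model, 3 SEACR intervals passed.

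Averaged over the 3 treatments, KO organoids had lower H3K27ac scores than WT at fetal-like and regenerative genes, and also at housekeeping genes. Strong intervals fell in KO in general, and each gene is represented by its strongest interval. Of 20 bins of intervals by mean score, the highest had a median log2 change of -0.18, and -0.0070 after cyclic loess. Of 24 fetal-like genes 21 were lower (median log2 change -0.28, -0.17 relative to all genes), among them S100a6 (-0.49 ± 0.11), Il1rn (-0.50 ± 0.11), Sprr2a3 (-0.28 ± 0.066) and an interval 15526 bp from Ereg, which encodes epiregulin (-0.43 ± 0.11). The list passed (adjusted camera p = 0.00142; adjusted p = 0.815 with an estimated correlation), and 11 of its genes passed when adjusted over the list alone, against 0 over all intervals. Sprr2a3 lost its direction after cyclic loess (0.027). All 16 housekeeping genes were lower too (median -0.30; adjusted camera p = 0.00458; adjusted p = 0.815 with an estimated correlation), among them Ywhaz (-0.43 ± 0.11), Ppia (-0.53 ± 0.15) and Eef2 (-0.46 ± 0.15), and 4 passed when adjusted over the list alone. Both lists passed without each of the 12 libraries in turn (0.000496 to 0.0123 and 0.00160 to 0.0284) and after quantile normalization and cyclic loess (0.0442 for the fetal-like list after the latter).

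Single genes of other lists were also lower in KO when adjusted over the list alone, uncorrected for the general fall of strong intervals. In the Wnt list these were Rnf43 (-0.51 ± 0.10, adjusted p = 0.000649) and Lgr4 (-0.36 ± 0.10, adjusted p = 0.0132), in the enterocyte list the transcription factor genes Cdx2 (-0.55 ± 0.11, adjusted p = 0.000689) and Hnf4a (-0.36 ± 0.10, adjusted p = 0.0269), and in the stem cell list 6 genes, with Lrig1 (-0.41 ± 0.098, adjusted p = 0.00570) and Ascl2 (-0.40 ± 0.13, adjusted p = 0.0226) among them. Among cAMP targets 4 passed, led by the phosphodiesterase gene Pde4b (-0.67 ± 0.14, adjusted p = 0.00187) and with Fos (-0.41 ± 0.11, adjusted p = 0.00426). The AP-1 list had 4, the PPAR list 5, the proliferation list 1 (Mcm3, -0.42 ± 0.12) and the endothelial list 1 (Pecam1, -0.43 ± 0.12). The intervals of Fos and Mcm3 lay 36363 and 27408 bp from their gene spans. Tead1, the DNA-binding partner of YAP, passed over all intervals (-0.61 ± 0.11, adjusted p = 0.0360) as the sole list gene to do so.

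These lists did not move as wholes relative to other genes. Adjusted camera p was 0.371 for the stem cell, YAP, cAMP, AP-1, PPAR, interferon, NF-kB and fibroblast lists, 0.180 for proliferation (19 of 20 lower, median -0.16) and Paneth, 0.471 for enterocyte and goblet, 0.663 for tuft, 0.709 for Wnt and endothelial, 0.770 for eicosanoid and 0.774 for immune. The eicosanoid, tuft, interferon and immune lists had negative medians with a test that pointed up. Enteroendocrine genes moved the other way, with 9 of 15 higher in KO (median 0.098, adjusted camera p = 0.0241; adjusted p = 0.419 with an estimated correlation), led by Scg3 (0.46 ± 0.17) and Cpe (0.37 ± 0.14), of which none passed when adjusted over the list alone. Over the alternatives its adjusted p ranged from 0.00932 to 0.419. The call was lost with only intervals near gene ends (0.166), after quantile normalization (0.0660) and cyclic loess (0.335), and without WT vehicle replicate 2 (0.0735), WT PGE2 replicate 1 (0.0645), KO vehicle replicate 1 (0.0748), KO AA replicate 2 (0.0963) or KO PGE2 replicate 2 (0.105). The list also had the lowest signal of the 20 over all libraries together, though not in each group.

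**Figure D2:**
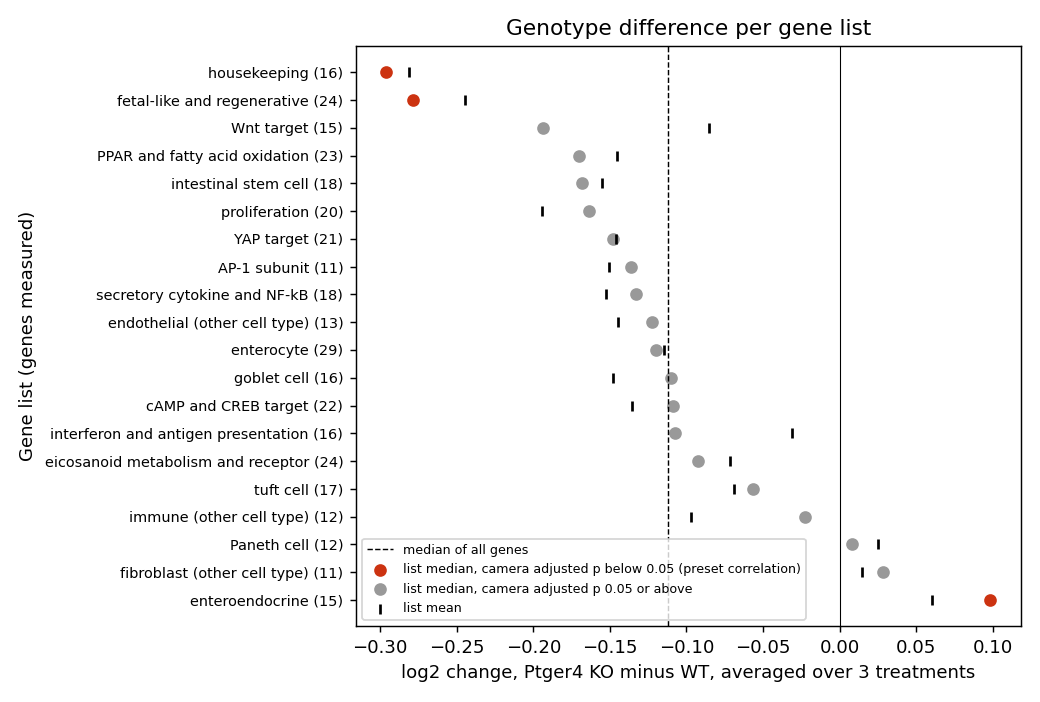
Points give the median and bars the mean log2 change of KO against WT, averaged over 3 treatments, for each of 20 gene lists, with the median of all genes as a dashed line. The fetal-like (-0.28) and housekeeping (-0.30) medians lie lowest and the enteroendocrine median (0.098) highest.

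In this averaged comparison 71 of 166471 intervals passed in limma, 19 higher and 52 lower in KO. Among the losses with an assigned gene, the smallest p-values lay near Col19a1 (the interval named above; -1.33 ± 0.11, adjusted p = 4.13e-07), at Mid1, a microtubule-bound ubiquitin ligase gene (X, 169990794 to 170009217; -1.03 ± 0.12, adjusted p = 0.000145), near Nkx2-6 (chromosome 14, 69161992 to 69162453; -0.85 ± 0.12, adjusted p = 0.00367), and at Myh9, the non-muscle myosin gene (chromosome 15, 77813181 to 77826806; -0.96 ± 0.14, adjusted p = 0.00417), with an interval assigned to Txn2 beside it (-0.93 ± 0.13, adjusted p = 0.00417). The gains lay mostly on chromosome 19, where 16 of the 19 higher intervals were found: near Ide, the insulin-degrading enzyme gene (37342221 to 37342961; 1.14 ± 0.17, adjusted p = 0.00466), at Btaf1 (36949058 to 36961228; 0.93 ± 0.14, adjusted p = 0.00466), at the mitotic kinesin gene Kif11 (37372248 to 37379660; 0.76 ± 0.12, adjusted p = 0.00731), near Marchf5 (0.95 ± 0.15, adjusted p = 0.00794) and at Fgfbp3 (0.84 ± 0.16, adjusted p = 0.0375). Dlg2 on chromosome 7 also rose (1.03 ± 0.17, adjusted p = 0.0148).

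The other named intervals were lower in KO. Rel, an NF-kB subunit gene, fell by 0.71 ± 0.11 on the log2 scale (chromosome 11, 23745802 to 23747515; adjusted p = 0.00908), Card6 by 1.11 ± 0.17 (chromosome 15, 5106490 to 5108746; adjusted p = 0.0075), the death adaptor gene Cradd by 0.97 ± 0.15 (adjusted p = 0.00814), Gm10037 by 1.08 ± 0.17 (adjusted p = 0.00731) and the interval near Abhd2 by 1.04 ± 0.17 (adjusted p = 0.00944). Rel scored 0.141 ± 0.0297 (SD, n = 6) in KO and 0.269 ± 0.0470 in WT, Btaf1 0.227 ± 0.0166 and 0.0920 ± 0.0115, and the Col19a1 interval 0.895 ± 0.242 and 2.32 ± 0.446. In 63 of the 71 intervals every library of one genotype lay above every library of the other, and the 71 were selected by the same difference. Of the 71, 39 lay within a gene span, 24 within 50 kb of one and 8 farther away. All 16 named intervals passed after quantile normalization, median centring and cyclic loess. Of all 71, 55 still passed after quantile normalization, 67 after median centring and 41 after cyclic loess.

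The number that passed moved with each library. It was 28 without WT vehicle replicate 1, 16 without WT vehicle replicate 2, 19 and 22 without WT AA replicate 1 or 2, 24 and 26 without WT PGE2 replicate 1 or 2, 32 and 15 without KO vehicle replicate 1 or 2, 12 and 13 without KO AA replicate 1 or 2, 1482 without KO PGE2 replicate 1 and 149 without KO PGE2 replicate 2. Col19a1, Mid1, Nkx2-6, Txn2 and Myh9 passed without each library. Ide and Btaf1 passed in 10 of 12 such fits (highest adjusted p = 0.0587, without KO AA replicate 2), Kif11 and Marchf5 in 9, Gm10037 and Card6 in 8, Cradd in 7, Abhd2 in 5, Rel in 4, Dlg2 in 3 and Fgfbp3 in 2 (highest adjusted p = 0.230, without KO vehicle replicate 1). The split into 19 higher and 52 lower was 33 and 40 after quantile normalization, 28 and 54 after median centring and 46 and 22 after cyclic loess. Without a trend in eBayes 0 passed in limma (smallest adjusted p = 0.112), against 71 with it, and 13516 had an unadjusted p under 0.05, against 15160 with it. Of 701 MACS2 intervals 8 passed, all lower.

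Of the 71 intervals, 24 sat in 4 runs with gaps of up to 100 kb. In 2 runs on chromosome 19 the KO score was about 2 times that of WT: from 36914629 to 36973284 (Fgfbp3 and Btaf1; 5 of 13 intervals passed, ratio 2.29) and from 37239047 to 37379660 (Marchf5, Ide and Kif11; 11 of 24 passed, ratio 2.14), with ratios of 1.20 and 1.21 in their flanks. The run at Myh9 and Txn2 on chromosome 15, from 77813181 to 77883276, was lower in KO at 9 of 9 intervals, of which 5 passed. Relative to the median score of all intervals in a library, its level was 0.783 ± 0.0825 (SD, n = 6) in KO and 1.85 ± 0.191 in WT. The run at Mid1, from 169990794 to 170017922, was lower at 3 of 3 intervals, and all 3 passed. Its relative level was 0.991 ± 0.211 in KO and 2.42 ± 0.316 in WT. The runs were picked for intervals that passed between the genotypes in the same libraries, so these levels describe the runs and do not test them.

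**Figure D3:**
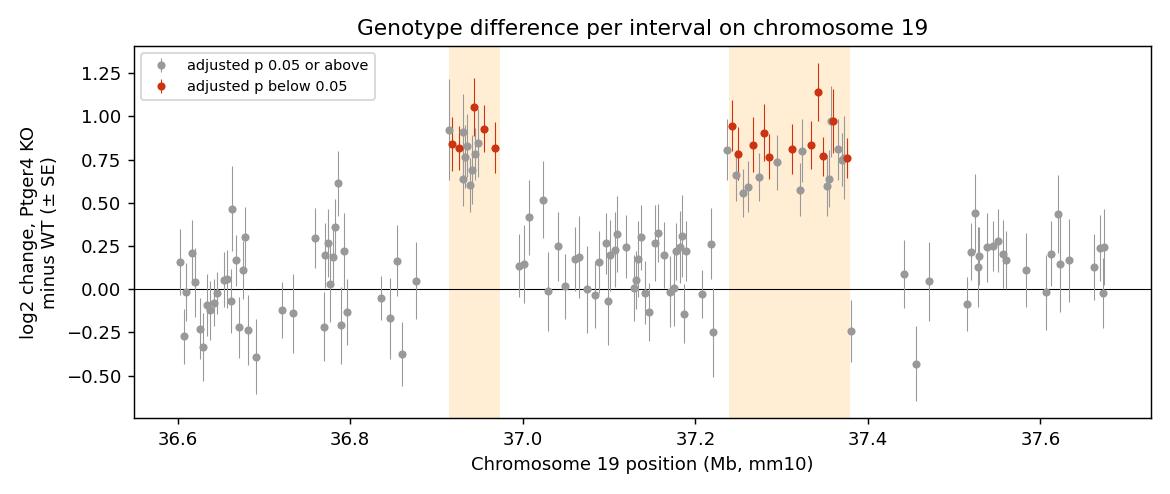
Log2 change (± SE) of KO against WT, averaged over treatments, for each interval by its position in Mb on chromosome 19, with passing intervals in red and the 2 runs shaded. Inside the shaded spans the intervals that did not pass also lie above 0.

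The level of chromosome 19 as a whole was higher in KO. Each score was divided by its interval's mean over the 12 libraries, and the median over the chromosome, runs left out, was divided by that over all autosomes; this level was 1.05 ± 0.0142 (SD, n = 6) in KO and 0.963 ± 0.00880 in WT, a ratio of 1.09, with every KO library (1.03 to 1.06) above every WT library (0.951 to 0.972). The exact two-sided permutation p was 0.00216, the smallest that 924 splits can give, and 0.0216 after Benjamini-Hochberg adjustment over the chromosomes. Chromosomes 3, 11, 12, 16 and 18 also passed, with ratios between 0.979 and 1.01. In 13 windows of 5 Mb along chromosome 19, with the runs left out, the ratio was 1.04 to 1.12.

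**Figure D4:**
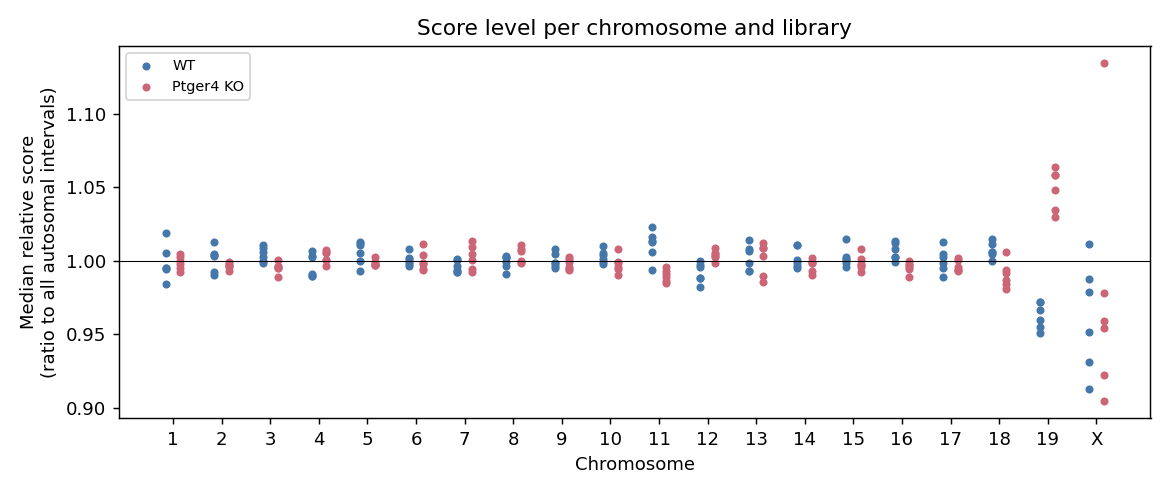
Points give, for each chromosome and library, the median relative score as a ratio to all autosomal intervals, coloured by genotype. Chromosome 19 lies at 1.03 to 1.06 in KO and at 0.951 to 0.972 in WT.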

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

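Leaving KO PGE2 replicate 2 out of comparisons that do not contain it was chosen only after its values were seen.

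Of 12 sets of 6 libraries examined (6 measures in each genotype), 4 had a library that lay apart, where chance gives about 5% of sets. In all 4 it was KO PGE2 replicate 2, set against the other 5 KO libraries. Its median SEACR score was 0.0941 (nearest KO library 0.113) and its median MACS2 score 0.268 (nearest 0.419). Its mean Spearman correlation with the other libraries in the SEACR intervals was 0.157 (nearest 0.293), whereas in the MACS2 intervals it was the highest of the 12 libraries (0.599). The 8 strongest SEACR intervals held 17.8% of its signal (nearest 8.64%). These measures come from the same library and may be related. Whether signal gathered in a few intervals lowers the rest depends on how the score was scaled, which is not given.

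This library enters the KO PGE2 comparison, where Areg (-0.88 ± 0.21), Batf (-0.95 ± 0.24) and Tek (-0.87 ± 0.20) were lower when adjusted over their lists alone. KO PGE2 replicate 1 was the next library in SEACR correlation and in the share of the strongest intervals. No explanation of the position of replicate 2 itself was tested.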

How the results depend on the processing

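Cyclic loess, the MACS2 intervals, quantile normalization for the gene lists, the intervals above the median mean score for library similarity, and leaving out KO PGE2 replicate 2 where it was not compared were chosen only after the results were seen. Of 270 values of 22 results under the alternatives, 224 stayed and 46 moved. For counts, staying meant an equal number or one within 1.5 times. A result with 0 passing in both fits therefore counted as staying. For the correlation of AA and PGE2 changes and the similarity of libraries, it meant a small difference. The cause was not tested for the moved values given here, except that fewer intervals or libraries entered some fits.

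For KO AA, 4 intervals passed when only the compared libraries were fitted, against 0. For KO PGE2, 3 passed after quantile normalization, 1 after median centring, 2 after cyclic loess, 3 with the larger pseudocount, 4 with a replicate block and 19 of the MACS2 intervals, against 0; leaving out 1 library gave 0 to 175, the latter without KO PGE2 replicate 1.

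For KO against WT with vehicle, 3 passed after quantile normalization, 0 after median centring, 2 after cyclic loess, 0 above the median mean score, 0 without a trend (limma), 2 with only the compared libraries and 3 of the MACS2 intervals, against 1; leaving out 1 library gave 0 (without WT vehicle replicate 2 or either KO vehicle replicate) to 3 (without KO PGE2 replicate 2). In the main test 7569 intervals had an unadjusted p under 0.05.

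For KO against WT averaged over treatments, 31 passed above the median mean score, 0 without a trend (limma; 13516 intervals at an unadjusted p under 0.05) and 8 of the MACS2 intervals, against 71; leaving out 1 library gave 12 (without KO AA replicate 1) to 1482 (without KO PGE2 replicate 1, with all 71 among them). The block gave 56.

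For the AA interaction, 1 passed with only the compared libraries, and leaving out 1 library gave 0 to 2 (without KO PGE2 replicate 2). For the PGE2 interaction, 1 passed after quantile normalization, and leaving out 1 library gave 0 to 30 (without KO PGE2 replicate 1). No interval passed for WT AA, WT PGE2 or AA against PGE2 under any alternative run.

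Of the gene lists, 1 passed for WT PGE2 with all intervals per gene, 1 after cyclic loess and 1 after quantile normalization, against 0. With an estimated correlation 0 passed for the averaged genotype comparison, against 3. With only intervals near gene ends 1 passed for the PGE2 interaction and 1 for AA against PGE2.

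The top 500 intervals above vehicle in WT AA had a KO median relative to all intervals of -0.0025 after median centring and -0.0020 after cyclic loess, and those below vehicle in WT PGE2 had 0.017 after cyclic loess. Similarity within groups was 0.601 in the MACS2 intervals.

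Each single named interval gave a value under each alternative, with most Ptger4 intervals counted apart. Of these values 4 reversed, 94 weakened, 50 strengthened and 5337 stayed. Staying meant the same sign and the same side of the threshold, so an interval that failed in both fits also stayed. Sprr2a3 (averaged genotype) went to 0.027 after cyclic loess. Flt4 (KO AA) ranged from -0.20 without KO AA replicate 2 to 1.55 without replicate 1, Cdx2 (vehicle) from -0.51 without WT vehicle replicate 1 to 0.010 without replicate 2, and Pgk1 (vehicle) from -0.20 without KO vehicle replicate 2 to 0.94 without replicate 1. At the Ptger4 intervals counted apart, 88 values reversed and 1088 stayed, and none of these intervals passed in the comparisons.

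Replicate numbers did not pair the libraries: residuals of same-numbered libraries correlated at -0.024 to 0.0097, and 0 of 15 pairs exceeded 0.1. The depth is unknown, and a 2-fold change was recovered in 1% of simulated intervals for WT AA and 28% for the averaged genotype comparison.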

Other observations

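The count over other splits of the libraries was set before its result was seen; all other tests in this part were chosen only after the result was seen.

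Further intervals that fell in KO organoids were chosen after their values were seen. Mmp14, a membrane metalloprotease gene, fell by 0.86 ± 0.15 on the log2 scale (SE; adjusted p = 0.0277 in limma), the kinase gene Map3k2 by 0.63 ± 0.11 (adjusted p = 0.0159), Ski, a repressor of TGF-beta signalling, by 0.57 ± 0.11 (adjusted p = 0.0365), and the TGF-beta induced gene Tsc22d1 by 0.67 ± 0.12 (adjusted p = 0.0360). The intervals at the mitotic checkpoint gene Bub3 (-0.59 ± 0.11, adjusted p = 0.0300) and the heat shock gene Hspa1b (-0.62 ± 0.12, adjusted p = 0.0360) were lower too.

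Some passing intervals had scores far above those of other intervals. The MACS2 interval near Col19a1 from 24613319 to 24613955 scored 1.21 ± 0.430 (SD, n = 6) in KO and 3.27 ± 0.775 (SD, n = 6) in WT. This stretch of chromosome 1 is known as a nuclear copy of mitochondrial DNA, so reads from mitochondria can map there, and the start of chromosome 9, where 15 MACS2 intervals passed in KO PGE2, holds repeats. Mid1 spans the edge of the pseudoautosomal region. These are background facts from outside the data, and none was tested here.

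The 71 genotype calls were more than other splits of the libraries gave. Of 100 splits balanced over treatments, 1, the real one, gave 71 or more; the highest other split gave 4, and 89 gave 0. This count covers only these 12 libraries. It cannot exclude chance differences between cultures or animals, since the labels do not say whether the libraries came from separate ones. Genotype and culture line coincide in this design, so a difference between the lines and an effect of losing EP4 are both open.

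Along the chromosome 19 runs at Fgfbp3, Btaf1, Marchf5, Ide and Kif11, an extra copy of the segments and H3K27ac gained at strong elements alone were set against each other. With gaps of up to 500 kb, 83.1% of 59 intervals that did not pass were higher in KO, and the log2 score ratio of the weaker intervals was -0.67 relative to the stronger. With gaps of up to 100 kb, a rule chosen after those outcomes, 100% of 21 such intervals were higher and the weaker intervals were 0.23 above the stronger (1.24 and 1.00). The spans are cut by where the passing intervals lie. The later rule leaves out a stretch at Cpeb3 where none passed, and the rules disagreed. Over the longer span copy number and strong elements cannot be told apart. Inside the 2 shorter spans the intervals that did not pass had median log2 changes of 0.77 and 0.66. Their flanks had 0.17 ± 0.23 and 0.19 ± 0.20 (SD over intervals). Those 2 spans were cut around passing intervals of the same libraries by the later rule. The gain at their weaker intervals therefore cannot decide between strong elements alone and an extra copy. At Myh9 and Txn2 on chromosome 15, 100% of 4 such intervals were lower; a later rule asked for at least 10 intervals, and copy number and regulation cannot be told apart there because the intervals are too few. The segment around Ide and Fgfbp3 is known, from outside the data, to vary in copy number among C57BL/6J mice; DNA copy number was not analysed here, and an effect of EP4 loss stays open and untested.

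Outside the runs, 44 intervals such as Rel, Card6 and Tead1 were lower in KO (median log2 change -0.77), and most were strong (median score at percentile 97.5). The profile of the KO libraries tended to be flatter, with overlap between the genotypes. The strongest intervals stood at -0.70 relative to the weakest in KO PGE2 replicate 2, -0.064 to 0.061 in the other KO libraries and 0.028 to 0.29 in WT. Another measure, the 99th percentile of scores over the median, ranged from 2.06 to 2.70 in KO and from 2.18 to 2.57 in WT. Its highest value was in KO PGE2 replicate 1. After each library's trend was removed 15 of the 44 passed and the median shrank by 20.5%, just over the 20% set as the bound. The flatter profile may therefore explain part of these calls. The 29 that ended went from -0.63 (SE 0.115) to -0.46 (SE 0.0958). They were picked because they no longer passed, so their shrinkage is no further support. A second test, chosen after the first was seen, left the median at -0.61 (95% bootstrap interval -0.77 to -0.47), beyond the bound of -0.38. It cannot decide whether the flatter profile was the whole cause. The 44 were selected for a large fall in these same libraries, and the bootstrap resampled intervals, not libraries. Without KO PGE2 replicate 2 the median of the 44 was -0.72, so their fall did not rest on that library alone. They were selected with the other libraries included, which made a fall without it likely. An effect of genotype or culture line stays open.

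The level of chromosome 19 in KO was 1.09 times that in WT. Of its 13 windows of 5 Mb, 100% were higher in KO, as extra copies of the chromosome in part of the KO cells would give. After each library's trend was removed its median log2 change was 0.096, against 0.012 for the highest other autosome, which argued against the trend. A gain of chromosome 19 in part of the cells is a candidate explanation, and a broad effect of genotype on its genes stays open and untested.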
